A study of Mus musculus with 8 samples.

How the data were processed

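Gene expression was measured in embryonic mouse gonads on 8 Affymetrix MG_U74Av2 arrays, 1 for each combination of sex (male, female), genotype (wild type, WT; Wnt4 knock-out, KO) and stage (E12.5, E14.5). Per the labels, gonads were dissected and kept frozen until the embryos had been genotyped by PCR, total RNA was purified on RNeasy columns, and 8 µg of it was turned into biotin-labelled cRNA. The deposited values are log2 summaries of 12488 probe sets on each array. Per the submitters' processing notes they were made with MAS5; its version, its scaling target and any background step are not given in the sources used here. The unit was read from the deposited values, which lay between 2.36 and 15.0 on every array. Deposited array medians differed, from 7.04 to 7.85, so each array was centred on the common median. In the column of the KO male E12.5 array, 14 cells held whole numbers from 41278 to 41284, which are spreadsheet serial numbers of dates, and these cells were set to missing. Rspo1, Hes1 and Epb42 were among the genes affected.

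After centring, values under a floor at the 40th percentile of all values (6.99 on the log2 scale) were set to the floor, so that a difference between a pair of arrays with 1 at the floor is a lower bound, while a fitted value that includes such arrays depends on the floor. Probe sets above the floor on at least 2 arrays were kept and the 66 Affymetrix control probe sets were left out, which gave 8452 fitted probe sets for 6346 genes. The annotation gave 1 gene for 10833 probe sets, several for 396 and none for 1193, and 10817 of those with 1 gene were found in the RefSeq table with no symbol differing. Where a gene had several probe sets, the one with the highest mean over the 8 arrays stood for it.

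Comparisons were tested with limma 3.58.1 in R 4.3.3 on all 8 arrays with the model sex × genotype plus sex × stage, moderated variances with an intensity trend, and Benjamini-Hochberg adjustment over the fitted probe sets at 0.05, two-sided. No group held a replicate, so the 2 residual degrees of freedom come from the part of the genotype effect that differs between the stages within each sex, to which moderation added 2.77 prior degrees of freedom. Errors are SEs of that fit. A genotype effect that is real at 1 stage only therefore counts as error. From this fit came the KO effect in each sex and over both sexes, its difference between the sexes, the stage effect in each sex with its difference between the sexes, and the sex difference in each genotype (male minus female, averaged over the stages).

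Before the data were examined, 26 gene lists with 430 genes were fixed, of which 321 genes had a probe set. They were pregranulosa, Sertoli, Leydig and steroidogenic, adrenocortical, germ cell pluripotency, general germ cell, meiosis, male germ cell, endothelial, arterial and Notch, erythroid, macrophage, mesonephros and duct, coelomic epithelium, neural crest and nerve, smooth muscle and myoid, extracellular matrix, Wnt pathway, activin, BMP and TGF-beta, hedgehog, cholesterol synthesis, cell cycle, apoptosis and p53, immediate early and stress, hypoxia and glycolysis, and X- and Y-linked sex-check genes. Lists with at least 3 fitted genes were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry, with adjustment over the lists of a comparison. Camera and fry left out genes with a missing value, which took 1 gene from the pregranulosa (Rspo1), the arterial and Notch and the erythroid list. The pregranulosa list holds Wnt4, the gene knocked out, so part of its KO shifts is set by the design. The male germ cell and sex-check lists had 2 fitted genes each and were not tested. With an estimated correlation, camera takes its p-value from the residual degrees of freedom, 2 here, so that few lists could pass. At the preset correlation it uses the number of genes, which are not replicates of the gonads. The gap between these results is therefore not due to correlation alone. Within each list, probe sets were also adjusted over the list alone.

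Also without a test, probe sets at least 2-fold apart were counted for each pair of arrays that differ in 1 factor. A shift of KO gonads toward the other sex was measured at each stage as the median KO minus WT difference, signed toward the other sex, of the probe sets that differed 2-fold between WT males and WT females at the other stage. Its percentile was taken among 10000 random lists matched on mean level in 10 bins. These lists were drawn from probe sets of the same arrays, so the percentile does not measure the spread between arrays or embryos. Named genes followed a rule: Wnt4 and the sex-check genes; per comparison the 12 highest and 12 lowest passing genes whose pair differences had 1 sign; where fewer than 6 passed in a direction, up to 6 with the largest smaller pair difference; and up to 4 members per list. The model, the floor, the filter, the lists, the naming rule and the alternatives on normalization, floor, filter, intensity trend, stage term, probe set averaging, list test, fold threshold and single arrays left out were chosen before the data were examined. After that were added the fits without both E14.5 male arrays, a model with genotype within each stage (sex × stage plus genotype × stage), the comparison of control probe sets, the agreement of probe sets of 1 gene, the count of probe set names by suffix, and the shares of admixed RNA.

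Recovery was tested on simulated data with the fitted spread. Of changes simulated in KO females, 22.4% at 1.5-fold, 50.7% at 2-fold and 45.5% at 4-fold were recovered, and 45.8%, 92.3% and 100% among probe sets above the floor on all 8 arrays, with 2 false calls among 81. Over both sexes, 47.8%, 61.2% and 53.0% were recovered, all of those above the floor on all arrays, with 0 false calls among 108. These simulated changes were equal at both stages, which real ones need not be, and the noise was drawn independently for each probe set. Wnt4 itself, above the floor on all 8 arrays, did not pass in KO females or over both sexes. A KO count of 0 therefore does not show that 2-fold changes were absent.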

Results

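The data were expression values from gonads of WT and Wnt4 KO mouse embryos of both sexes at E12.5 and E14.5, the days over which the early gonad turns into a testis or an ovary. Each of the 8 combinations of sex, genotype and stage had 1 array and no replicate, and this number of arrays limits the precision of every value. Values are median-centred log2 signals, differences are log2, and errors are SEs of the limma fit. On each array, between 59.7% and 60.5% of the probe sets lay above the floor of 6.99.

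Wnt4, a secreted signal that the fetal ovary needs, had its highest level on the array of the WT female at E12.5 (10.19) and was at 8.59 in the KO female of that stage. The pair differences, KO minus WT, were -1.60 in females at E12.5, -1.14 in females at E14.5, -0.92 in males at E12.5 and -0.23 in males at E14.5. Whether the Wnt4 probe set lies in the deleted part of the gene is not given in the sources used here. Xist, the RNA that coats the inactive X chromosome of females, lay between 7.10 and 8.13 on the 4 female arrays and between 4.07 and 4.79 on the 4 male arrays. The Y-linked gene Eif2s3y, measured by a probe set of the kind shared within a gene family, lay between 6.91 and 8.12 on the male arrays and at 5.36, 6.04 and 4.86 on 3 of the female arrays. On the array labelled WT female E14.5 it was at 7.63, and Xist there was at 7.10, the lowest of the female arrays. Uty and Kdm5d, which are also Y-linked, did not rise above the floor on enough arrays to be fitted.

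**Figure D1:**
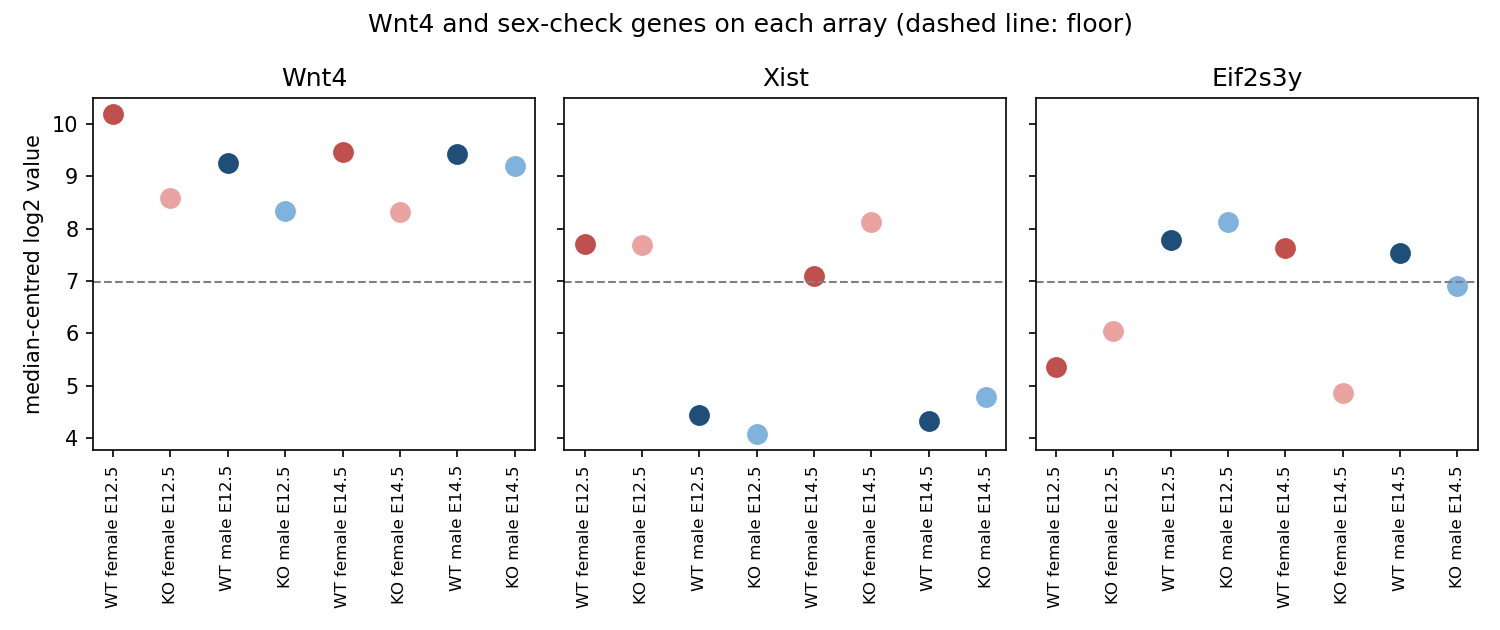
Median-centred log2 level of Wnt4, Xist and Eif2s3y on each of the 8 arrays, 1 point per array, with the floor of 6.99 as a dashed line. Eif2s3y lay at 7.63 on the array labelled WT female E14.5 and at or under 6.04 on the other female arrays.

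Across probe sets, the 6 arrays other than the E14.5 males correlated with each other at Pearson r of 0.979 to 0.997. The 2 E14.5 male arrays correlated with each other at 0.996 and with the other 6 arrays at 0.883 to 0.907. Genes are not independent replicates, so these values describe the arrays and carry no test. Between 1504 and 2085 probe sets differed at least 2-fold between an E14.5 male array and one of the other 6, against 9 to 151 between any pair of those 6. Control probe sets without a mouse transcript also lay apart after centring. The median of 19 such sets differed from the other arrays by 0.42 and 0.34 on the E14.5 male arrays, and by -0.15 to 0.18 on the rest. Centring had added 0.43 and 0.47 to the E14.5 male arrays and -0.34 to 0.09 to the rest, so the centring itself could give this gap. The male arrays also differed from the female ones in technical values at both stages. At E12.5 the mean of 9 spike-in probe sets was 9.48 and 9.78 in males and 8.85 and 8.83 in females. The 3' minus 5' gap of actin was 0.96 and 1.10 against 0.48 and 0.49. At E14.5 the spike-in mean was 9.98 and 10.09 in males and 8.88 and 9.05 in females. The actin gap was then 1.37 and 1.09 against 0.77 and 0.55. Both E14.5 male arrays stood apart, so an array-level difference and the state of the E14.5 testis cannot be told apart in any comparison that rests on them.

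**Figure D2:**
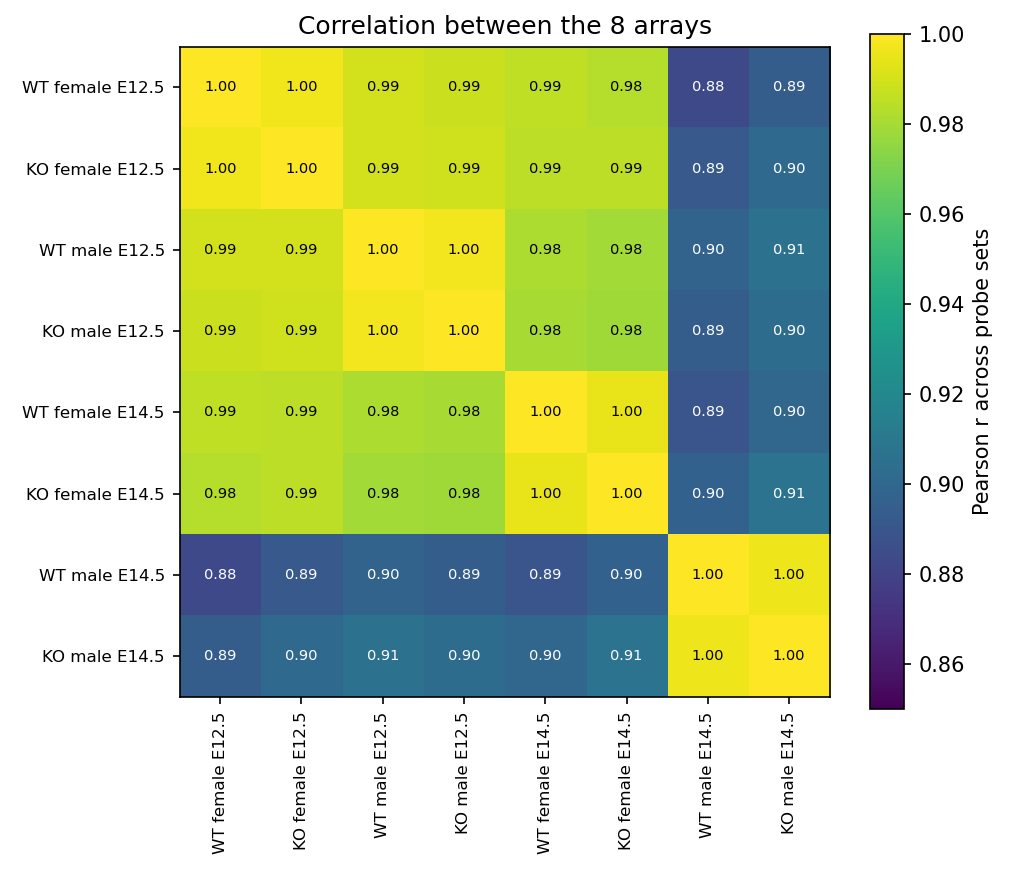
Pearson r between each pair of the 8 arrays, across all probe sets other than the controls, before the floor and the filter. The 2 E14.5 male arrays correlated with the other 6 at 0.883 to 0.907, while those 6 correlated among themselves at 0.979 or above.

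KO females were compared with WT females to ask which transcripts of the fetal ovary depend on Wnt4. The genes with the most negative differences at both stages were Irx3, a homeobox transcription factor of supporting cells in the ovary, at -1.79 ± 0.60, Fst, whose product follistatin binds and blocks activins, at -1.38 ± 0.27, and Wnt4 at -1.37 ± 0.20. Next came Apcdd1, a membrane protein that dampens Wnt signals, at -1.18 ± 0.46, Igfbp2, an insulin-like growth factor binding protein, at -1.05 ± 0.37, and Tnfrsf19, a receptor of the TNF family, at -0.97 ± 0.12, a value that depends on the floor. Positive differences at both stages were found for Lefty1, an inhibitor of Nodal, at 0.84 ± 0.07, Cxcl12, a chemokine that guides migrating germ cells, at 0.74 ± 0.28, the matrix protein gene Postn at 0.59 ± 0.11, the prostaglandin-degrading enzyme gene Hpgd at 0.54 ± 0.10, Gadd45a at 0.52 ± 0.10 and Rspo1, whose product enhances Wnt signals, at 0.43 ± 0.06. No gene passed the threshold. The 12 genes just given had adjusted p from 0.346 to 0.436.

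The KO minus WT pair differences at E12.5 and E14.5 were -1.93 and -0.83 for Fst, -1.57 and -0.79 for Apcdd1 and -1.39 and -0.72 for Igfbp2, and that of Irx3 was -2.58 at E12.5. For Lefty1 they were 0.83 and 0.86. Fst lay near the floor on the KO female arrays, at 7.09 and 7.42, and Irx3 did so at E12.5, at 7.03.

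Among the gene lists, pregranulosa genes, which mark the supporting cells of the ovary, shifted down in KO females as a group by camera, which left out Rspo1 for its missing value (adjusted p = 3.5e-05, median of all 8 genes -0.69), with adjusted p = 0.966 with an estimated correlation. Adjusted over the list alone, 7 of its 8 genes were lower and 1 was higher (Rspo1), while 0 passed over all probe sets. Wnt4, the gene knocked out, is 1 of the 7 lower genes, so this part of the fall is set by the design. The list was not tested without Wnt4. The lower ones included Msx1 (-0.72 ± 0.25), Kitl, the ligand of the Kit receptor (-0.67 ± 0.20), and Wnt6 (-0.64 ± 0.14). By the same test, extracellular matrix genes (adjusted p = 0.0032, 16 of 20 positive), macrophage genes (0.0045, 10 of 10 positive), arterial and Notch genes (0.011, 7 of 9 positive) and neural crest and nerve genes (0.044, 6 of 9 positive) shifted up. Hypoxia and glycolysis genes shifted down (0.0045, 13 of 13 negative), among them Hk2 at -0.44 ± 0.07 and Pdk1 at -0.41 ± 0.13. Each of these 5 lists had adjusted p = 0.966 with an estimated correlation. Adjusted over the list alone, 1 gene each was higher in germ cell pluripotency (Dppa5a, 0.57), apoptosis and p53 (Gadd45a) and male germ cell (Lefty1). On the same basis 1 gene each was lower in adrenocortical (Nr0b1, -0.29), male germ cell (Dnmt3a, -0.38), mesonephros and duct (Cldn7, -0.38) and hypoxia and glycolysis (Hk2). For apoptosis and p53 genes the test was positive while median and mean were negative, and for Wnt pathway genes too (0.993).

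The counts of 0 came from limma with 962 of 8452 probe sets at an unadjusted p under 0.05, and from 16 without a stage term to 1153 with a lower floor under other settings. Pair counts at single stages, which carry no test, gave 4 probe sets at least 2-fold higher and 15 lower at E12.5, and 3 higher and 16 lower at E14.5. Male-type transcripts stood high on the array labelled WT female E14.5, against which the E14.5 difference was taken: of the 22 probe sets at least 2-fold higher in males at E12.5 on the mean of WT and KO, 18 were lower in KO than WT females at E14.5 (median -0.70) and 9 at E12.5 (median 0.010). The steroidogenic genes Cyp17a1 (0.12 at E12.5, -2.22 at E14.5), Hsd3b1 (both arrays at the floor at E12.5, -1.30 at E14.5) and Cyp11a1 (at least 0.94 and -1.55) were lower at E14.5 only in these pairs.

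**Figure D3:**
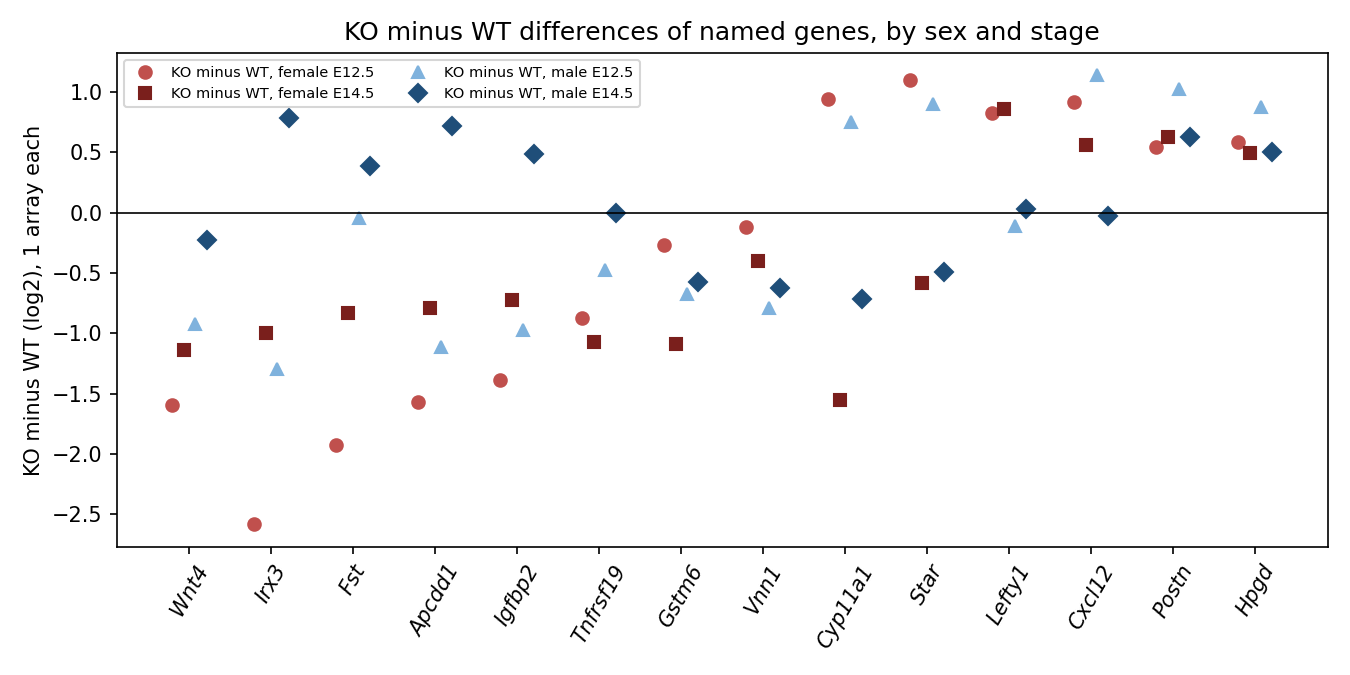
KO minus WT difference (log2) of 14 genes in each sex at each stage, 1 array against 1 array per point. Fst, for example, stood at -1.93 and -0.83 in females and at -0.05 and 0.39 in males; Cyp11a1 and Star were added to the plot after their values were seen.

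In males, the KO comparison asks what Wnt4 does in the fetal testis, where its level was lower than in the ovary at E12.5. Positive differences at both stages were found for Postn (0.82 ± 0.11), Hpgd (0.69 ± 0.10), the retinoic acid binding protein gene Crabp2 (0.57 ± 0.13), the prohormone-processing enzyme gene Cpe (0.50 ± 0.07), Reep1 (0.48 ± 0.07) and Mdfi (0.43 ± 0.07). Negative ones were found for Vnn1, a pantetheine-cleaving enzyme gene of Sertoli cells (-0.71 ± 0.09), the glutathione transferase gene Gstm6 (-0.63 ± 0.20), Thumpd1 (-0.62 ± 0.17), the neuropeptide gene Npy (-0.38 ± 0.13), Rab26os (-0.32 ± 0.07) and Gja1, which encodes the gap junction protein connexin 43 (-0.29 ± 0.06). None passed, each at an adjusted p of 0.793.

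As a group, Sertoli genes, the markers of the supporting cells of the testis, shifted down in KO males by camera (adjusted p = 2.2e-06, 15 of 15 negative, median -0.24), with adjusted p = 0.726 with an estimated correlation. In the fit with genotype within stage, over both sexes, the Sertoli list had a median of 0 at E12.5 (camera adjusted p = 0.701). At E14.5 it was down (2.7e-13, and adjusted p = 0.306 with an estimated correlation). At that stage the WT female and KO male arrays both held transcripts of the other sex. Members of the Sertoli list in males included Amh, the hormone that removes the female duct (-0.32 ± 0.11), and Hsd17b3 (-0.37 ± 0.17). Germ cell pluripotency (adjusted p = 0.012, 10 of 11 negative), cholesterol synthesis (0.023, 10 of 13 negative) and Leydig and steroidogenic genes (0.049, 10 of 12 negative) shifted down too. Endothelial genes shifted up (0.023, 13 of 14 positive), with Emcn at 0.44 ± 0.14 and Icam2 at 0.23 ± 0.06. All 4 had adjusted p = 0.726 with an estimated correlation. Over both sexes, Leydig and steroidogenic genes were up at E12.5 (1.7e-04) and down at E14.5 (7.6e-13) in the fit with genotype within stage, with adjusted p = 0.557 and 0.306 with an estimated correlation. The same WT female and KO male E14.5 arrays enter that fall. Adjusted over the list alone, 2 pregranulosa genes (Rspo1, Nr0b1), 2 coelomic epithelium genes (Upk3b, Lhx9), 1 extracellular matrix gene (Postn) and 1 adrenocortical gene (Nr0b1) were higher and 1 Sertoli gene (Vnn1) was lower. Rspo1 rests on the E14.5 pair (0.66), since its E12.5 value in KO males was missing. For the pregranulosa list median (0.06) and mean (0.04) were positive and the test negative (0.956), and for the matrix list the mean was positive while median and test were negative.

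The limma count of 0 in males stood beside 405 probe sets at an unadjusted p under 0.05, and 3 to 519 under the other settings with all arrays. At single stages, 6 probe sets were at least 2-fold higher and 3 lower at E12.5, and 3 higher and 2 lower at E14.5. On the KO male E14.5 array, female-type transcripts stood above those of the WT male: Irx3 was at 7.77 against 6.57, Kitl at 7.65 against 6.23 and Stra8 at 7.44 against 5.70.

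KO-by-sex differences, the male KO effect minus the female one, ask whether the sexes responded differently. Fst (1.55 ± 0.39), Irx3 (1.53 ± 0.85), the imprinted gene Phlda2 (1.03 ± 0.36), the retinoic acid binding protein gene Crabp1 (0.87 ± 0.14), Dusp9 (0.83 ± 0.30) and Hsd17b11 (0.81 ± 0.10) had the largest positive values at both stages. On the other side stood Lefty1 (-0.88 ± 0.10), the pluripotency marker Dppa5a (-0.57 ± 0.14), the desmosome gene Dsg2 (-0.45 ± 0.11), the inhibin subunit gene Inha (-0.39 ± 0.40), Gpr12 (-0.37 ± 0.07) and Tbc1d10a (-0.35 ± 0.10). None passed, at adjusted p from 0.434 to 0.647, and the sign for Inha turned when an E12.5 female or an E14.5 male array was left out.

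Pregranulosa genes had 8 of 8 positive differences between the sexes (median 0.73, camera adjusted p = 0.0036 without Rspo1), with Wnt4 itself among them. Germ cell pluripotency (0.0092), Sertoli (0.023) and extracellular matrix genes (0.028) shifted the other way. These 4 lists had adjusted p = 0.858 with an estimated correlation. Adjusted over the list alone, 2 pregranulosa genes and 1 adrenocortical gene were more positive in males and 1 male germ cell gene (Lefty1) was less so. Limma called 0 probe sets, with 971 at an unadjusted p under 0.05 and 5 to 1137 under the other settings with all arrays.

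Over both sexes, the matrix gene Postn (0.70 ± 0.07), Hpgd (0.61 ± 0.07), the growth factor gene Tgfb2 (0.51 ± 0.08), Cap1 (0.41 ± 0.13), the myosin light chain gene Myl7 (0.38 ± 0.07) and the matrix metalloproteinase gene Mmp14 (0.28 ± 0.08) were positive in all 4 KO pairs. Wnt4 (-0.97 ± 0.14), Gstm6 (-0.65 ± 0.14), Tent5c (-0.48 ± 0.13), the transcriptional co-regulator gene Cited1 (-0.36 ± 0.07), Gja1 (-0.34 ± 0.04) and Fhl1 (-0.25 ± 0.04) were negative in all 4. Their adjusted p ran from 0.556 to 0.841. Camera put pregranulosa (adjusted p = 1.5e-04, a list that holds Wnt4 itself), Sertoli (0.0011) and hypoxia and glycolysis genes (0.0045) lower. It put endothelial (0.0013), arterial and Notch (0.0045), neural crest and nerve (0.0045), macrophage (0.016), meiosis (0.023) and extracellular matrix genes (0.048) higher. All had adjusted p from 0.740 to 0.821 with an estimated correlation. In the fit with genotype within stage, Sertoli and meiosis genes had a median of 0 at E12.5 (camera adjusted p = 0.701 each). At E14.5 they had -0.36 (2.7e-13) and 0.12 (7.4e-04), with adjusted p = 0.306 and 0.471 with an estimated correlation. At that stage the WT female and KO male arrays held transcripts of the other sex. Limma called 0 probe sets, with 489 at an unadjusted p under 0.05 and 15 to 619 under the other settings with all arrays.

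When genotype was instead fitted within each stage, a model added after the data were seen in which the sexes act as the repeat, 5 probe sets rose and 2 fell in KO gonads at E12.5. They were Chgb, a granule protein of endocrine and nerve cells (1.18 ± 0.11), Cxcl12 (1.06 ± 0.10), Star, which carries cholesterol into mitochondria for steroid synthesis (pair differences of at least 1.10 in females and 0.90 in males), the neurofilament gene Nefm (0.58 ± 0.05), the adhesion molecule gene Vcam1 (0.56 ± 0.05), Igfbp3 (-1.06 ± 0.10) and Fhod3 (-0.59 ± 0.05), each at an adjusted p of 0.0433. All 7 were named after their values were seen. Both E14.5 pair differences of Chgb were 0, which arrays at the floor give. Nefm in females, and Vcam1 and Fhod3 in males, had an E14.5 difference of 0 as well. The fit pools the spread of both stages, so for these genes the SE and the passing depend on the floor. The Cxcl12 value is not from the probe set that stood for this gene elsewhere. That one gave 1.03 ± 0.15 and did not pass (limma adjusted p = 0.155). At E14.5 the count was 0, with 353 probe sets at an unadjusted p under 0.05, and 0 probe sets passed for the difference between the stages (303 unadjusted). The Star pair differences at E14.5 were -0.58 in females and -0.49 in males.

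Shifts of KO gonads toward the other sex were measured on probe sets chosen at the other stage. In KO females at E14.5, the 34 probe sets that differed 2-fold between WT males and WT females at E12.5 had a median shift of -0.15 toward the male level, below all of the 10000 random lists, with 10 toward and 23 away. Its parts went opposite ways: the 22 that were higher in males, a set chosen on WT alone, had a median KO minus WT difference of -0.55, away from the male level, and the 12 female-higher ones of -0.19, toward it. At E12.5, the 1833 probe sets taken from E14.5 had a median shift of 0.077 toward the male level, above all of the random lists, with 73.0% toward (median 0.048 for male-higher and -0.086 for female-higher ones). KO males shifted toward the female level at E14.5 by a median of 0.27 (24 of 34 toward, 4 away) and at E12.5 by 0.028 (59.0% toward), both above all random lists. Their male-higher and female-higher parts had median KO minus WT differences of -0.44 and 0.065 at E14.5, and of -0.0038 and 0.037 at E12.5. All random lists were drawn from probe sets of the same array pair. Their percentiles hold no spread between arrays or embryos, and an array-level difference could place a small shift above all of them. The E14.5 lists and the E14.5 shifts rest on the arrays that stood apart in the correlations or in their sex-check genes, and the female shift at E14.5 turned to 0.0076 with a 1.5-fold list.

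WT males were compared with WT females to ask what distinguishes the fetal testis from the fetal ovary. Among the genes higher in males by the largest amounts were those of Sertoli cells: Cst9, a cystatin, by 2.08 ± 0.21 and Amh by 1.48 ± 0.11, with Gstm6 by 1.45 ± 0.20 and the cartilage-type collagen gene Col9a3 by 1.43 ± 0.20. Among the 12 lowest in males were the pregranulosa list's Irx3 (-2.10 ± 0.60), Kitl (-2.03 ± 0.20) and Fst (-1.63 ± 0.27). Each of these 3 was at the floor on a male array, as Cst9 was on a female one, so that these values depend on the floor. Other genes that were higher included the imprinted RNA Meg3 (1.57 ± 0.26), the desaturase gene Scd1 (1.37 ± 0.13), the basement membrane gene Tinagl1 (1.25 ± 0.13) and the neural signal gene Cbln1 (1.25 ± 0.32). The other probe sets of Scd1 gave -0.94 and -0.09. Kcnj9, Sec14l2, Ankzf1 and Gpcpd1 completed the 12 highest. The differences of Meg3, Scd1, Kcnj9 and Sec14l2 were larger at E14.5, with stage by sex differences from 1.04 to 1.44. Those of Gstm6 and Ankzf1 were 0.23 and 0.59. Rars2, Eps15, Cbx6, Rab9, Nop16, Cstf2, 1810030O07Rik, Reep1 and Eloc completed the 12 lowest, at -1.57 to -1.85, and their differences lay mostly at E14.5: that of Rars2 was -0.38 at E12.5 and -3.31 at E14.5. Other probe sets gave 0.06 for Cbx6, -0.41 for Nop16, -0.64 for Eps15, -0.45 for 1810030O07Rik, and -0.47 and -0.42 for Eloc. Among the higher genes they gave -0.01 for Kcnj9, 0.58 for Sec14l2, 0.16 and 0.24 for Ankzf1, 1.09 for Meg3 and 0.95 for Gstm6.

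By list, 11 of 15 Sertoli genes were higher and 0 lower (camera adjusted p = 0.0011), with adjusted p = 0.972 with an estimated correlation. Of 8 pregranulosa genes 6 were lower, with Msx1 at -1.02 ± 0.25 (camera 0.259), and of 6 meiosis genes 5 were lower, among them Stra8, the switch gene of meiotic entry (-0.88 ± 0.19). General germ cell genes were lower for 3 of 4, with Ddx4 at -0.51 ± 0.08 and Dazl at -0.75 ± 0.15, for which a second probe set gave 0.16. Leydig and steroidogenic genes were higher for 3 of 12, with Nr5a1 at 0.85 ± 0.11 and the hedgehog target Gli1 at 0.80 ± 0.18, and both male germ cell genes, Dnmt3a (0.63 ± 0.10) and Lefty1 (0.59 ± 0.07), were higher. Within Sertoli genes the stages differed for Aard, at 2.14 at E12.5 and -0.05 at E14.5, where the female array was the one labelled WT female E14.5.

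In all, 2549 probe sets were higher and 2825 lower in WT males at an adjusted p under 0.05, of which 3563 had 1 sign at both stages; 69 and 240 differed at least 2-fold. The count was 0 when both sexes shared a stage term or had none, and 2370, 2601, 2638 and 2699 without the WT male E14.5, WT female E14.5, WT female E12.5 and WT male E12.5 array. With values as deposited 37.3% of the calls were higher, against 47.4% after centring. The pair at E12.5, free of the E14.5 male arrays, had 22 probe sets at least 2-fold higher and 12 lower, against 650 and 1183 at E14.5. Spike-in levels and actin gaps differed between male and female arrays at both stages. A technical part of the sex differences in WT and in KO therefore stays open.

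KO males and KO females differed in many of the same markers. Cst9 (2.18 ± 0.21), Col9a3 (1.52 ± 0.20), the Sertoli gene Aard (1.45 ± 0.34) and Amh (1.24 ± 0.11) were higher in males, as did the retinaldehyde dehydrogenase gene Aldh1a1 (1.51 ± 0.42) and Cyp17a1, the enzyme that opens androgen synthesis (1.80 ± 0.55). Gstm6, Scd1, Ddx54, Ankzf1, Tinagl1 and Sgpp1 completed the 12 highest. Rars2 (-1.59 ± 0.07), Shroom3, Tm9sf2, the lysosome membrane gene Lamp2, Cbx6, Eps15, Eloc, Rab9, 1810030O07Rik, Cstf2, Mef2d and Nop16 were the 12 lowest in males, the last at -1.38 ± 0.08. The differences of Lamp2, Cbx6, Eps15, Eloc, 1810030O07Rik and Nop16 lay mostly at E14.5, with stage by sex differences from -2.16 to -2.71. Other probe sets gave -0.44 and 0.02 for Scd1, 0.14 and 0.39 for Ankzf1 and 0.35 for Gstm6. Among the lower genes they gave 0.29 for Cbx6, -0.05 for Nop16, -0.49 for Eps15, -0.40 for 1810030O07Rik, -0.76 for Lamp2, and -0.22 and -0.44 for Eloc. In contrast to WT, where it was higher in males, Lefty1 was lower in KO males than in KO females (-0.29 ± 0.07); the KO-by-sex difference of Lefty1 had an adjusted p of 0.434. Xist was lower in KO males (adjusted p = 0.0282); its fitted difference of -0.93 is set by the floor, under which both KO male arrays lay.

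Of 15 Sertoli genes 10 were higher and 0 lower (camera adjusted p = 0.015), with adjusted p = 0.986 with an estimated correlation. Pregranulosa genes were lower for 3 of 8, among them Kitl (-1.11 ± 0.20) and Rspo1 (-0.47 ± 0.08), and higher for 1, Wnt6 (0.58 ± 0.14). Meiosis genes were lower for 5 of 6 (Stra8 -0.97 ± 0.19) and general germ cell genes for 3 of 4 (Dazl -0.86 ± 0.15, second probe set 0.085), while 4 of 12 Leydig and steroidogenic genes were higher. The counts were 2599 higher and 2238 lower, 2802 of them with 1 sign at both stages. They fell to 0 without the KO female E12.5 array or with a shared or no stage term, and were 1202, 1463 and 1728 without the KO female E14.5, KO male E12.5 and KO male E14.5 array. With values as deposited 32.7% of the calls were higher, against 53.7%. At E12.5 alone 29 probe sets were at least 2-fold higher and 4 lower, and at E14.5 596 and 908.

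At E12.5 in the fit with genotype within stage, over WT and KO, 450 probe sets were higher in males and 379 lower. Sertoli genes led by camera (adjusted p = 2.5e-07), with adjusted p = 0.568 with an estimated correlation. The pair differences in WT and KO were at least 2.32 and 2.29 for Cst9, 2.14 and 2.19 for Aard, and 1.37 and 1.22 for Amh.

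**Figure D4:**
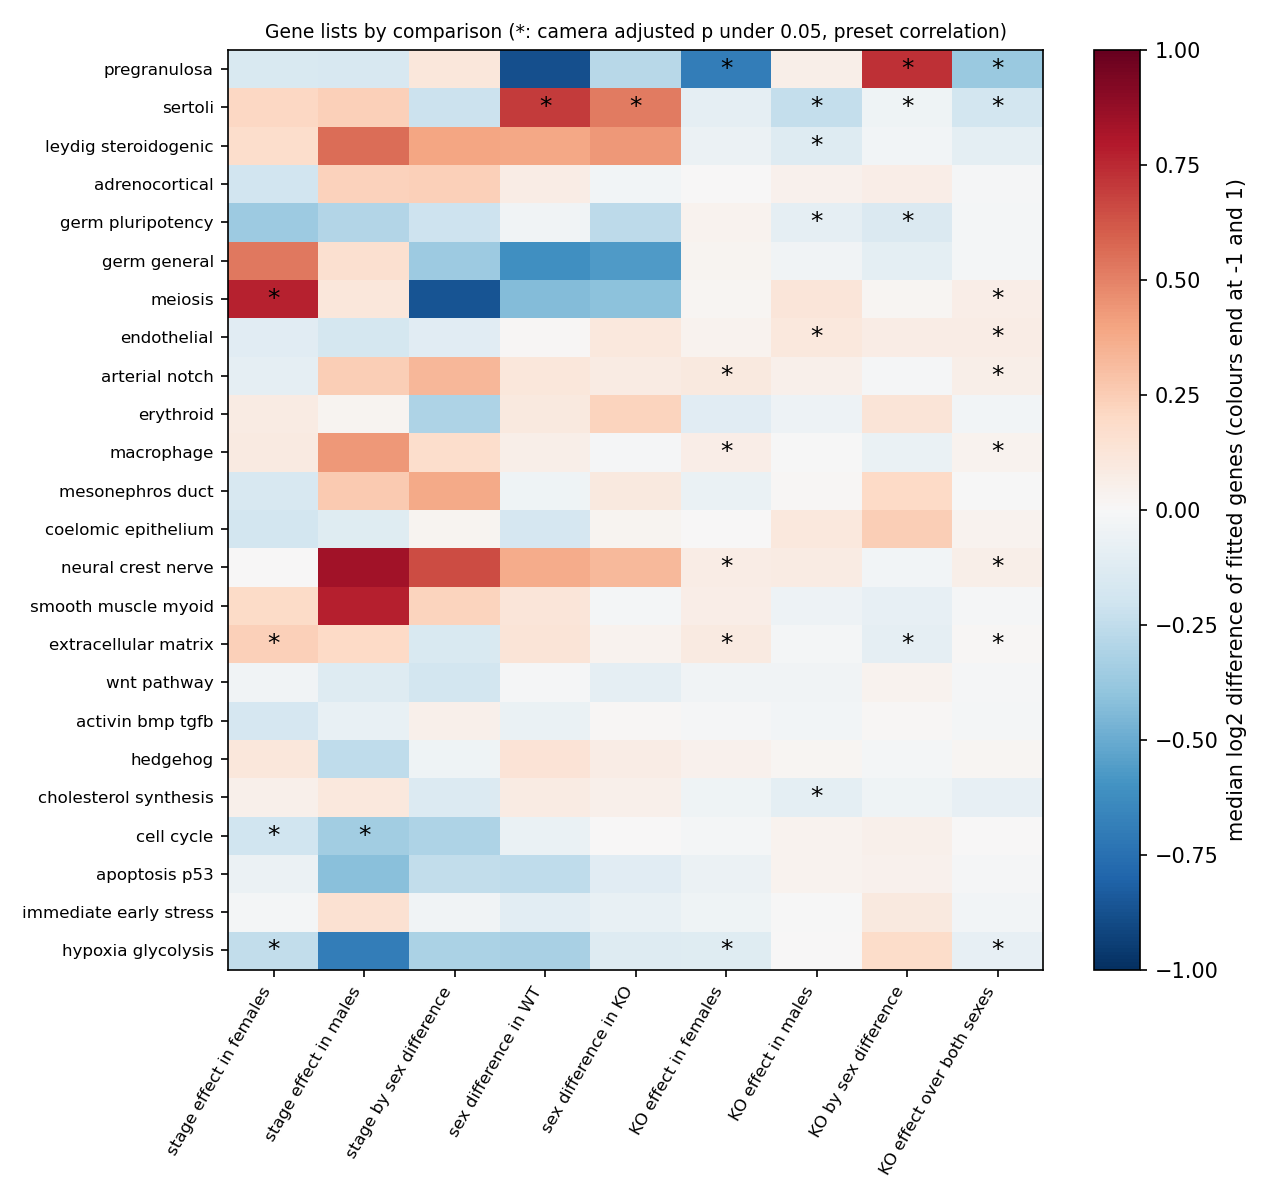
Median log2 difference of the fitted genes of each list (vertical axis) in each comparison (horizontal axis), with colours that end at -1 and 1. An asterisk marks a camera adjusted p under 0.05 with the preset correlation. With an estimated correlation 0 of the 31 marked shifts passed, in a test on 2 residual degrees of freedom that few lists could pass.

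From E12.5 to E14.5, germ cells in the ovary enter meiosis, and genes of meiosis were among the rises in females. Stra8 rose by 2.08 ± 0.19, the cohesin gene Stag3 by 1.39 ± 0.07, the oocyte transcription factor gene Figla by 0.80 ± 0.03, the recombination gene Brca2 by 0.75 ± 0.07 and the germ cell helicase gene Ddx4 by 1.57 ± 0.08. The pluripotency genes Kit (-1.23 ± 0.11) and Nanog (-1.11 ± 0.13) fell, while their list did not pass as a group. Among matrix genes, 8 of 20 rose, with Lum at 1.51 ± 0.06, Ogn at 1.45 ± 0.10 and the elastin gene Eln at 1.31 ± 0.14. The largest rises also held the MHC class I genes H2-K1 (2.57 ± 0.29) and H2-D1 (2.14 ± 0.26), Inca1 (2.49 ± 0.19), the enkephalin gene Penk (2.22 ± 0.21), the transcription factor gene Nfix (2.08 ± 0.13), Spata5, Fmr1nb and the smooth muscle gene Tagln (1.49 ± 0.18). A second probe set gave 0.62 for H2-K1 and 0.24 for Penk. The values of Stra8, Figla, Nanog and Ogn depend on the floor.

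Among the falls were the embryonic globin gene Hba-x (-1.65 ± 0.21), Sprr2d (-1.70 ± 0.12), the growth gene Hmga2 (-1.48 ± 0.18), the neurotrophic co-receptor gene Gfra3 (-1.48 ± 0.11), the stromal factor gene Foxd1 (-1.47 ± 0.32), Gadd45g (-1.23 ± 0.07) and the duct gene Gata3 (-1.12 ± 0.10). Those of Sprr2d, Gfra3, Foxd1 and Gata3 depend on the floor. Kyat3, Igf2bp1 and Slc38a4 were the others of the 12 lowest. All 6 meiosis genes rose (camera adjusted p = 4.6e-06), and matrix genes, of which 1 fell, shifted up (0.0017). Cell cycle genes fell for 9 of 20 and rose for 1 (0.023), with Plk1 at -0.79 ± 0.05 and Bub1 at 0.76 ± 0.06, and hypoxia and glycolysis genes fell for 6 of 13 (0.012), with Vegfa by 0.84, a value that depends on the floor. All 4 lists had adjusted p = 0.786 with an estimated correlation. Adjusted over the list alone, the counts were 6 of 6 higher for meiosis, 9 higher and 3 lower for matrix, 1 and 11 for cell cycle and 0 and 6 for hypoxia.

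Of the lists that did not pass, germ cell pluripotency had 1 gene up and 4 down of 11, coelomic epithelium 4 down of 8 (Aldh1a2 -0.79 ± 0.12, Lhx9 -0.70 ± 0.07), mesonephros and duct 3 down of 14, erythroid 4 up and 3 down of 11 (median 0.08, mean -0.09, test positive), and macrophage 2 up and 1 down of 10. Leydig and steroidogenic genes had 0 of 12 passing: Cyp17a1 stood at 3.04 in WT and 0.69 in KO females, and the WT value rests on the array labelled WT female E14.5. In total 711 probe sets rose and 1238 fell, and 46 and 18 did so at least 2-fold. All had 1 sign in both genotypes, which the model fixes, since a stage effect that differs between the genotypes counts as error. The count fell to 0 when any 1 of the 8 arrays was left out, which leaves 1 residual degree of freedom, and without both E14.5 male arrays; it was 40 without a filter. With values as deposited it was 5156, of which 5.24% rose. Without centring, the median of all fitted probe sets lay at -0.27 for the stage effect in females, -0.69 for that in males and -0.41 for their difference, so that directions here are relative to the median of each array.

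In males, the stage comparison follows the testis as its Leydig cells begin to make steroids. Genes of that pathway led the rises: Cyp17a1 by 3.45 ± 0.55, Hsd3b1 by 2.44 ± 0.39 and Cyp11a1, which makes the first steroid from cholesterol, by 2.30 ± 0.66. Rrad (2.05 ± 0.12), Cited1 (1.86 ± 0.10), the detoxifying hydrolase gene Ephx1 (1.86 ± 0.15), Mep1b, Sprr2b, the surfactant protein gene Sftpb, the keratin gene Krt17, Tcea2 and the mevalonate kinase gene Mvk followed. The strongest falls were those of the splicing factor gene Srsf11 (-3.25 ± 0.07), Arih1 (-3.24 ± 0.06), Wsb1 (-3.19 ± 0.09), Plagl1 (-3.10 ± 0.07), Lrrc58, Nr2f1, the condensin gene Smc2 (-2.85 ± 0.10), the translation factor gene Eif4a2 (-2.77 ± 0.05), Rars2, Mapk6, F2r and Hnrnpr. The values of Hsd3b1, Rrad, Arih1, Wsb1, Plagl1, Nr2f1, Smc2 and Rars2 depend on the floor. Other probe sets of the same genes gave -1.41 for Arih1, -0.74 for Plagl1, and -0.98 and 0.45 for F2r. For the rises they gave 1.60 for Krt17, 0.40 for Tcea2 and 0.96 for Mvk.

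Cell cycle genes fell for 15 of 20 and rose for 1 (camera adjusted p = 0.030), with adjusted p = 0.916 with an estimated correlation; Bub1 fell by 1.85, with the floor entering on an E14.5 array, Mcm4 by 1.83 and Pcna by 1.60. Steroidogenic genes rose for 5 of 12 and fell for 2, and Sertoli genes rose for 7 of 15 and fell for 4. Neural crest and nerve genes rose for 6 of 9 and fell for 2 (Uchl1 1.22 ± 0.10, Chga 1.17 ± 0.08), smooth muscle and myoid genes rose for 6 of 8 and fell for 1 (Acta2 1.51 ± 0.31), and macrophage genes rose for 7 of 10 and fell for 2 (Cd14 0.99 ± 0.08). Endothelial genes fell for 6 of 14 and rose for 3 (Cdh5 -1.65 ± 0.11), hypoxia and glycolysis genes fell for 9 of 13 and rose for 1 (Pkm -1.14), and apoptosis and p53 genes fell for 6 of 10 and rose for 0 (Apaf1 -1.29 ± 0.06). None of the lists other than cell cycle passed camera in this comparison. The lists with genes on both sides were, as up and down counts, arterial and Notch 3 and 2 of 9, erythroid 2 and 4 of 11, mesonephros and duct 6 and 3 of 14, coelomic epithelium 2 and 1 of 8, extracellular matrix 6 and 5 of 20, Wnt pathway 3 and 6 of 16, activin, BMP and TGF-beta 5 and 8 of 22, hedgehog 2 and 3 of 6, cholesterol synthesis 5 and 3 of 13, immediate early and stress 5 and 4 of 16, adrenocortical 2 and 1 of 5, germ cell pluripotency 3 and 5 of 11, general germ cell 1 and 1 of 4, meiosis 2 and 1 of 6 and pregranulosa 1 and 2 of 8. Both male germ cell genes rose, and 0 of 2 sex-check genes passed. For coelomic epithelium median and mean were negative and the test positive, and for erythroid the median was positive while mean and test were negative.

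In total 3209 probe sets rose and 3369 fell, with 612 and 1153 at least 2-fold. Both E14.5 male arrays stood apart on control probe sets too, a gap that centring could give. Probe sets of 1 gene also differed in this comparison. Over 1085 genes with 2 probe sets their effects correlated at r = 0.334, against 0.455 in females. Of 263 genes with a 2-fold effect, 75 had a second probe set of opposite sign. Probe sets with the suffix that marks relaxed design rules made up 26.0% of those at least 2-fold higher and 1.47% of those lower, against 5.22% of those fitted. With values as deposited 11.1% of the calls were rises, against 48.8% after centring.

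The stage effect differed between the sexes in meiosis genes: Stra8 had a male minus female difference of -1.85 ± 0.26, with 5 of 8 arrays at the floor, Brca2 of -1.19 ± 0.10 and Stag3 of -0.94 ± 0.10, and 5 of 6 genes passed (camera adjusted p = 0.245). Kitl (-2.26 ± 0.29) and the angiotensin receptor gene Agtr2 (-2.65 ± 0.41) were lower in this sense, and Wnt4 was higher (1.01 ± 0.28, adjusted p = 0.0268). At the head of the higher genes were Sprr2b (2.31 ± 0.09), Tcea2, Naglu, Mvk, Sprr2d, Rsph1, Sftpb, Tln1, Mep1b, Clip1, Krt17 and Ror1. Other probe sets gave -0.32 and 0.97 for Tln1, 0.40 for Tcea2, 0.86 for Mvk and 1.33 for Krt17. Srsf11 (-2.96 ± 0.09), Lrrc58, Rbbp4, Rars2, Eif4a2, Arih1, Plagl1, Ppic, Nop16, Rab9 and Cstf2 were lowest with Agtr2. Other probe sets gave -0.86 for Arih1, -0.47 for Plagl1 and -0.14 for Nop16. Cell cycle genes split, 4 higher and 9 lower of 20, and none of the tested lists passed camera. Counts were 2978 higher and 2857 lower, and with values as deposited 18.1% of the calls were higher against 51.0%; both E14.5 male arrays enter each of these differences.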

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

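Of the tests in this part, the Y-linked and Xist levels, the control probe sets, the 3' to 5' gaps, the implied shares of ovary RNA and the other splits of the arrays were chosen after the results were seen. The predictions on KO ovaries at E12.5 and on probe sets of 1 gene were written before their values were computed, though after the patterns had been noticed.

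The array labelled WT female E14.5 held male-type transcripts: Eif2s3y lay 1.59 above the highest other female array, and Cyp17a1, Aard and Cst9 were above the KO female of that stage. A male embryo labelled as female is argued against by Xist, which lay 2.31 above the highest male array. RNA of male gonads in this sample is a candidate explanation. Its implied share was 24.5% as the median of 17 Sertoli and steroidogenic genes (range -21.0% to 106%) and 55.0% from Xist. These shares took the KO female E14.5 array as ovary and the WT male E14.5 array as testis. An effect of the KO would count as admixture in them. No share was computed from Eif2s3y. Its level there, 7.63, lay above the WT male (7.54) and KO male (6.91) of E14.5 and under the E12.5 males (7.77 and 8.12). A mixture with RNA like that on the E14.5 male arrays would lie below them. The markers therefore give no common share, and the E14.5 male arrays, which stood apart, are an uncertain reference. Lower expression of male-type genes in KO ovaries could also lower the KO minus WT difference at E14.5. The prediction for this was a negative median of male-type probe sets at E12.5, and any other median was to count against it. At E12.5 the median of 22 male-type probe sets, chosen on the mean of WT and KO, was 0.00982, with 9 of them lower. That lies on the side against it. A sign test that the prediction did not name did not pass, and an effect at E14.5 alone was not tested, so this was left undecided. The KO effect in females, the stage effect in females and the sex difference in WT all rest on this array.

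The 2 E14.5 male arrays stood apart from the other 6. After centring, control probe sets without a mouse transcript differed by a mean of 0.377 on these arrays and lay outside the range of the other 6. Centring had added 0.43 and 0.47 to these 2 arrays, against -0.34 to 0.09 on the other 6. This value therefore cannot decide on an array-level effect. RNA degradation needed wider 3' to 5' gaps of both actin and Gapdh on both arrays: the smaller Gapdh gap was -0.0869 and the other -0.02, under those of the other 6, while actin had its widest gap of all arrays, 1.37, on the WT male and 1.09 on the KO male, inside the range of the other 6 (0.48 to 1.10). The effects of 2 probe sets of 1 gene correlated at 0.334, between the values set in advance for and against a signal that leaves the gene, so these cannot be told apart. Both arrays are of 1 group, so the state of the E14.5 testis stays open as well, and the 5835 probe sets of the stage by sex difference rest on them.

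The array labelled KO male E14.5 held female-type transcripts, with Irx3, Kitl and Stra8 above the WT male. Ovary RNA in this sample could bring them: Xist implied a share of 2.87%, the meiosis genes 12.7% over 5 genes and the pregranulosa genes 33.5% over 3. The KO female E14.5 array stood for the ovary in these shares and the WT male E14.5 array for the testis. Irx3 and Kitl were fitted lower in KO than in WT females, which would raise the pregranulosa share. Xist lay under the floor on both E14.5 male arrays, so its share decides nothing. Irx3, Kitl and Stra8 also lay under the floor on the WT male array, so the shares that use them are uncertain too. Ovary RNA and an effect of the KO on these genes cannot be told apart. Wnt4 was at 9.19 on this array, against 9.42 on the WT male of E14.5. It was at 8.34 on the KO male of E12.5 and at 8.32 on the KO female of E14.5. The array therefore shows little loss of the transcript of the knocked-out gene, and the data give no other check of its genotype. The KO effects in males rest on this array.

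Over both sexes the KO count was 0, and 35 of the 35 splits of the 8 arrays into 4 and 4 gave at least as many; with a real count of 0 this outcome was fixed, and it says nothing on chance. The highest other split, of the stages, gave 6202 probe sets, that of the sexes gave 5947 and that of E12.5 females with E14.5 males gave 5718, and every other split gave 7 or fewer. These 3 splits keep each WT and KO pair together and place both E14.5 male arrays on 1 side, so the structure they point to is not separated from an array-level effect on those arrays.

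The KO-by-sex differences of gene lists had camera adjusted p of 0.00355 for pregranulosa, a list that holds Wnt4, and 0.00916 for germ cell pluripotency. They had 0.0228 for Sertoli and 0.0283 for extracellular matrix genes, and all had adjusted p = 0.858 with an estimated correlation. The control probe set for the 5' end of 18S ribosomal RNA was 1.92 higher on the KO male E12.5 array than on the WT male one, at 8.90 against 6.98.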

How the results depend on the processing

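The fits without both E14.5 male arrays and with genotype within each stage are tests chosen after the results were seen; the other alternatives were planned. KO and WT arrays were compared within sex and stage, and no further pairing was possible because each group holds replicate 1 only. The KO counts were 0 in each sex, by sex and over both sexes under every alternative run on the sex-by-genotype model, with smallest adjusted p from 0.0614 upward; with genotype within each stage, 7 probe sets passed at E12.5. Of the comparison-level results, 189 values stayed, 57 moved and 1 turned in direction, and of the single-gene values 4601 stayed, 521 were weaker, 37 stronger and 5 reversed. Those 5 were Inha, whose KO-by-sex difference of -0.39 became 0.0619 without either E12.5 female array and 0.0199 without either or both E14.5 male arrays, with a range of -0.843 to 0.0619 over single arrays left out. The cause of the shifts was not tested unless stated.

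With values as deposited the stage effect in females had 5156 calls instead of 1949, and the 2-fold pair counts were 2 for KO minus WT in males at E14.5, 179 for stage in WT females, 2909 in WT males and 3070 in KO males; the array medians, which centring takes out, differ by stage and sex. Without a filter it had 40, the sex difference in KO had 3223 instead of 4837, and gene lists past the threshold numbered 20 instead of 31. The lists numbered 0 with an estimated correlation, a test that rests on 2 residual degrees of freedom, and 14 with fry. With a shared stage term and with no stage term the sex differences in WT and in KO had 0 calls each, since the residual then holds the stage difference between the sexes.

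With 1.5-fold lists the shift toward the other sex was 0.0076 for KO females at E14.5, which turned its direction, 0.0570 at E12.5, and 0.0949 and 0.0191 for KO males at E14.5 and E12.5. With 3-fold lists it was -1.05 for KO females and 0.50 for KO males at E14.5. With quantile normalization it was 0.0418 for KO females and 0.00577 for KO males at E12.5.

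With the floor at the 20th percentile, 2-fold pair counts were 33 for KO minus WT in females and 9 in males at E14.5, 59 for male minus female in WT and 55 in KO at E12.5, and 154 for stage in WT females and 135 in KO females. With the floor at the 60th percentile they were 10 and 8 for KO minus WT in females at E12.5 and E14.5, and 5 and 2 in males. For male minus female they were 21 and 998 in WT and 20 and 778 in KO, and for stage 47 in WT females, 1002 in WT males, 49 in KO females and 985 in KO males. A lower floor shows more, and a higher floor fewer, differences among weak signals by construction.

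With 1 array left out, 1 residual degree of freedom stays and the lone sample is assumed to vary like the other groups. The stage effect in females then had 0 calls without any of the 8 arrays (0 to 0), and 0 without both E14.5 male arrays. The sex difference in WT ranged from 2370 to 4511, with 2370 without the WT male E14.5, 2601 without the WT female E14.5, 2638 without the WT female E12.5 and 2699 without the WT male E12.5 array. The sex difference in KO ranged from 0 to 3796, with 0 without the KO female E12.5, 1202 without the KO female E14.5, 1463 without the KO male E12.5 and 1728 without the KO male E14.5 array. The stage effect in males ranged from 4982 to 6146 and its difference between the sexes from 4130 to 4402. The stage comparisons were not run with a shared or no stage term, nor the male stage and sex comparisons without both E14.5 male arrays.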

Other observations

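The tests in this part come from the fit with genotype within each stage and were chosen after the results were seen. At E12.5 the genes that passed in KO gonads included Star and Chgb. Star was higher by at least 1.10 in females and by 0.90 in males, and Chgb, a protein of secretory granules, by 0.94 and 1.41. The SE of Chgb depends on the floor. Cyp11a1 did not pass and had differences of at least 0.94 and 0.75. Cyp17a1 had 0.12 and -0.07. Th, the first enzyme of catecholamine synthesis, had differences of 0.62 and 0.54 (adjusted p = 0.0699), and Mc2r, the receptor for the hormone that drives the adrenal cortex, had 0.31 and 0.47 (adjusted p = 0.119).

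By camera, the lists that shifted up in KO gonads at E12.5 included neural crest and nerve (adjusted p = 1.7e-06) and Leydig and steroidogenic genes (1.7e-04). Pregranulosa genes, a list that holds Wnt4 itself and was tested without Rspo1 for its missing value, shifted down (8.0e-10). These lists had adjusted p = 0.557 with an estimated correlation. Lists of other cell types shifted as well: endothelial (0.0019), smooth muscle and myoid (0.0030), extracellular matrix (0.0030) and macrophage genes (0.018) up, and mesonephros and duct genes down (0.0030), with adjusted p from 0.557 to 0.637 with an estimated correlation. At E14.5 Sertoli (2.7e-13) and Leydig and steroidogenic genes (7.6e-13) were down, with adjusted p = 0.306 with an estimated correlation, and there the WT female and KO male arrays both held transcripts of the other sex. Pregranulosa genes did not pass at E14.5 (median -0.11, adjusted p = 0.297).

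Cells of the adrenal in or beside the KO gonad are a candidate source of these E12.5 transcripts. Of the adrenocortical and the neural crest and nerve list, the larger camera adjusted p at E12.5 was 0.0476, that of the adrenocortical list, with adjusted p = 0.557 with an estimated correlation. The median of the adrenocortical list was 0, so that a few genes such as Mc2r carry it, and Nr0b1 is also in the pregranulosa list. Lists of other cell types shifted too, so the values are not specific to the adrenal, and adjacent tissue left on the dissected gonad could give them and was not tested.

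Over both genotypes at E12.5, Aldh1a1, which makes retinoic acid, was 1.73 ± 0.24 higher in males (adjusted p = 0.0167), Me1 was 1.86 ± 0.17 higher (0.0065) and Sprr2d 1.59 lower (0.0021). By camera, erythroid (8.9e-04), extracellular matrix (0.0028), Leydig and steroidogenic (0.0033) and endothelial genes (0.0051) were higher in males and pregranulosa genes lower (0.042), with adjusted p from 0.568 to 0.825 with an estimated correlation. Spike-in levels and actin gaps differed between male and female arrays at E12.5 as well, so a technical difference between the sexes stays open for these values.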
